A study of Drosophila melanogaster with 6 samples.

How the data were processed

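RNA was measured by sequencing in 6 pools of Drosophila melanogaster larvae 36 h after egg laying, 3 of wild type (w1118) and 3 of animals carrying the 18603 mutation of SRm160 (CG11274) in the w1118 background. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the TruSeq RNA kit, and flies were kept at 25°C with 12 h of light. The series design text gives 150 larvae of each genotype moved to food at 24 h and collected 12 h later as 3 groups of 100, numbers that do not add up. Nothing in the labels says that the pools came from separate cultures, so p-values measure only the spread between these pools.

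Per the submitters' processing notes, TopHat2 2.1.1 and edgeR 3.14.0 were used. The genome build, the annotation, the counting program and whether strand was used in counting are not given in the sources used here, and coordinates below are those of the deposited tables. The authors deposited whole-number counts of reads per gene and per bin, an exonic bin being a stretch of a locus between neighbouring exon boundaries. Bins are numbered E for exonic and I for intronic sequence. By their coordinates, I bins can hold exonic bins of the same gene, so that a stretch can be tested as both: 3254 of the I bins in the table and 2578 of those tested overlapped an exonic bin of their gene. An event of start or end was read as a transcript start or end, and exonic bins that some transcripts lack carry an event type (skipped exon, retained intron, alternative 5' or 3' site, or several). All alternative bins also stood in the exon table, and each bin was used once. Because I bins can hold exonic bins, the summed bin counts of a locus count some reads more than once. Counts of exonic bins sum to more than gene counts, so some reads were counted in more than 1 bin. The authors' deposited tables of altered genes and bins hold log2 fold changes and p-values, with no replicate values, and were used only for comparison with the calls made here. The authors' deposited summary of Gene Ontology enrichment holds p-values, with some cells given only as above a limit. The deposited lists of genes behind that summary were not used here.

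Genes were tested in R 4.3.3 with edgeR 4.0.16 (TMM normalisation, filterByExpr with its minimum count of 10, quasi-likelihood F test, two-sided, no covariate). P-values were adjusted by Benjamini-Hochberg and called under 0.05. Of 14239 genes, 836 had no count and 11369 were tested. Log2 changes are mutant minus wild type, and CPM values use TMM-scaled library sizes. Bins were tested against the other bins of their locus with diffSpliceDGE, in loci with at least 2 tested bins, with adjustment over all 67824 bins. A bin's usage is its percent of all bin counts of its locus. Where all libraries of a group had 0 counts, a bound was computed from 3 counts over the group. Such bounds cover counting error only. Gene lists, 36 in all, were tested with camera of limma 3.58.1 with a preset correlation of 0.01 between genes where at least 5 members were tested (35 lists; the list of mitochondrially encoded genes had fewer), with an estimated correlation and fry as alternatives. Symbols of the deposited tables were matched to current names through a RefSeq table, 10558 directly, 3341 through synonyms and 340 not at all. The intron share of each library was compared by an exact two-sided permutation test, which cannot go below p = 0.1 with 3 against 3. Overlap of bins and genes was found from the deposited coordinates with GenomicRanges 1.54.1.

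Designs, lists and the alternatives were fixed before the data were examined, except those named as chosen later. The alternatives were DESeq2 1.42.0, limma voom, other size factors, filters and thresholds, the replicate letter as a block, and leaving out each library. Named genes were SRm160, w, the 5 neighbours of SRm160 on each side, the 10 largest rises and falls among called genes with a mean of 10 CPM or more in the higher group, non-overlapping groups and a symbol other than a CG or CR number, and up to 4 called members of each list by smallest p. Named bins were the 5 largest rises and falls per bin class with a mean count of 20 or more in the higher group, at most 1 per gene, and called bins of SRm160 and of sex determination genes. The text gives a part of these.

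The tests were tested on simulated data. For the gene comparison, with 11297 genes in the step, edgeR recovered 11.2% of 98 genes changed by 0.5 on the log2 scale and 67.7% of 99 changed by 1, with 1 false call. Far more genes were called in the data than were changed in the simulation, so the simulation faced a stricter adjusted threshold. Its shares are not the power of the comparison below. The bin comparison had 59937 bins in the step. There edgeR recovered 40.8% of 98 bins changed by 1 and 87.9% of 99 changed by 2. These were 40 and 87 bins, against 20 false calls in loci without a changed bin, the only loci where false calls were counted. False calls thus made up a larger share of the simulated bin calls than the adjusted threshold allows. The bin calls below may likewise hold more false ones than that threshold states. No pair of replicates agreed within sampling noise (chi-square per degree of freedom from 22.5 to 141), so each library was counted once.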

Results

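The data were read counts per gene and per bin for 3 wild type and 3 SRm160 mutant pools of larvae. SRm160 encodes a nuclear protein rich in serine and arginine that takes part in splicing. Gene counts summed to 56029852, 57923952 and 49148401 in wild type A, B and C and to 54983164, 49971971 and 44086394 in mutant A, B and C. Along the first principal component, which held 66.1% of the variance of log2 CPM, the genotypes separated. The second held 19.2% and set wild type A apart from wild type B and C.

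SRm160 itself (3L, 13029926 to 13034076) was detected in every library and was lower in the mutant. It stood at 65.4 ± 3.21 CPM in wild type (SD, n = 3) and 51.6 ± 1.9 CPM in the mutant (SD, n = 3), a log2 change of -0.34 (SE 0.06, edgeR adjusted p = 0.00572). Counts were 3569, 3850 and 3166 in wild type A, B and C and 2950, 2635 and 2183 in mutant A, B and C. None of the 4 tested SRm160 bins was called relative to the gene with edgeR (0 at an unadjusted p under 0.05) or with voom (1 at an unadjusted p under 0.05). With a minimum log2 change of 0.58 the call on SRm160 would be lost. The eye pigment transporter gene w had 0, 0 and 4 counts in the wild type libraries and 880, 603 and 633 in the mutant libraries (log2 change 9.01, SE 0.56, edgeR adjusted p = 0.000181). Wild type C held all 4 of the wild type counts, so without it that group stood at 0 and no size of change is given (edgeR adjusted p = 0.000433). The labels give the w1118 background, which carries a deletion in w, for both genotypes. That background alone does not account for the w counts of the mutant libraries. Where these reads come from was not tested, so they do not show that the stated background is wrong. Of 10 genes that flank SRm160, 9 were tested and 4 were called: Syx13 rose by 0.68, while CG11253 (-0.79), CG17672 (-2.74) and snoRNA:Psi28S-3327c (-1.41) fell on the log2 scale. The snoRNA lies inside RpS4, so reads of the pair cannot be told apart.

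The comparison of the genotypes asks which transcripts differ with the SRm160 mutation. Apart from w, several of the large rises among named genes were in enzymes of detoxification and metabolism. Cyp6a17, a cytochrome P450, went from 2.67 ± 0.1 to 87.6 ± 16.2 CPM (SD, n = 3 each), a log2 change of 5.04 (SE 0.17). Its exonic bin E002, annotated as a transcript end, had 0, 0 and 2 counts in wild type A, B and C. In mutant A, B and C that bin had 1596, 1422 and 890 counts, a rise beyond that of the gene. Whether a difference between strains at this gene takes part in its rise was not tested. The P450 genes Cyp9b2 (log2 4.54, SE 0.19), Cyp28d2 (4.39, SE 0.15), Cyp28a5 (3.00, SE 0.16) and Cyp12a5 (2.72, SE 0.20) rose as well, as did the lipase gene Lip3 (3.23, SE 0.12), the thioester protein gene TepIV (2.50, SE 0.10) and a histone gene copy, His2A:CG33832 (3.09, SE 0.12). The phosphoenolpyruvate carboxykinase gene CG10924 (Pepck2) went from 2.8 ± 0.594 to 121 ± 15.3 CPM (SD, n = 3 each), a log2 change of 5.43 (SE 0.19). The highest adjusted p among these genes was 0.000279 (edgeR).

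The named falls included cuticle and molting genes, while the fixed lists did not pass with all libraries: of 93 cuticle protein genes 15 rose and 17 fell (median log2 change 0.28, camera adjusted p = 0.659), and of 23 ecdysone response genes 6 rose and 12 fell (camera adjusted p = 0.0906). Without wild type A the ecdysone list passed (camera adjusted p = 0.00428, adjusted p = 0.526 with an estimated correlation, a combination chosen after seeing the data), and the cuticle list did not (camera adjusted p = 0.382). On the log2 scale, the cuticle protein genes Cpr47Ed (-3.57, SE 0.73), Cpr67Fa1 (-2.78, SE 0.36) and Cpr49Ag (-2.69, SE 0.20) fell, as did the denticle gene sha (-3.22, SE 0.66), the serine protease-like gene mas (-2.93, SE 0.62) and the ecdysone-responsive nuclear receptor gene Hr46 (Hr3, -2.88, SE 0.38). The highest adjusted p among them was 0.00915 (edgeR). The tal-1A and tal-2A entries, which lie on the same transcript and had identical counts, also fell (-2.72, SE 0.43). Wild type A was far below B and C for several of them: sha stood at 14.2 CPM there against 56.9 and 59.3, and mas at 53.9 against 280.3 and 206 CPM. Cpr67Fa1 went the other way, at 39.1 CPM in wild type A against 18.6 and 16.7 CPM in B and C. For Cpr49Ag the wild type libraries lay closer together, at 277, 314 and 365 CPM against 49.7, 37.5 and 61.5 CPM in the mutant.

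**Figure D1:**
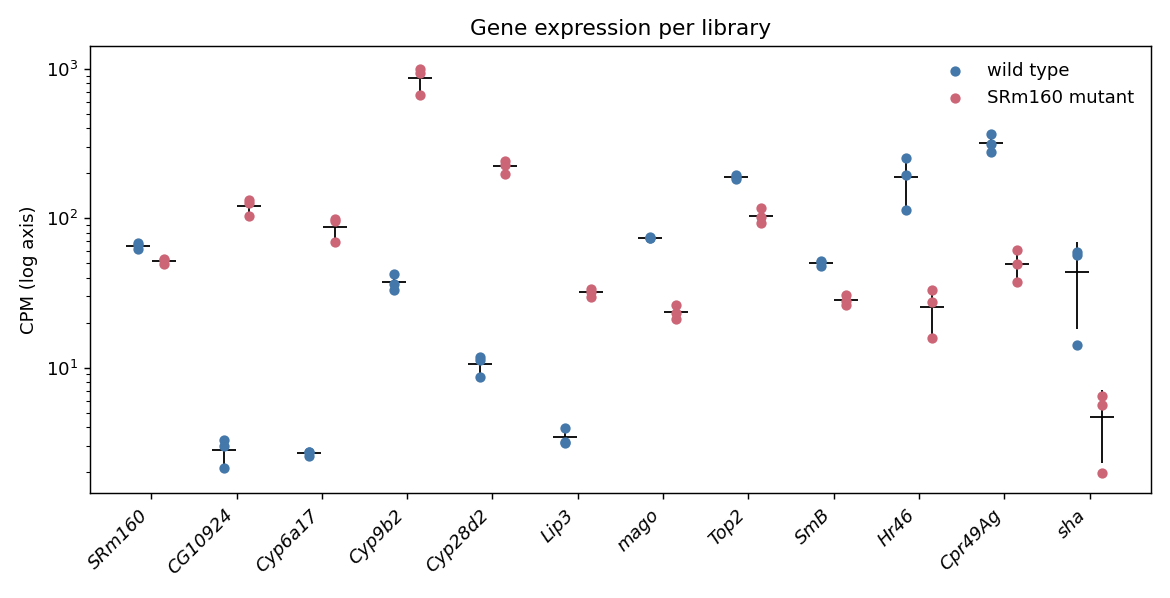
CPM per library on a log axis for 12 genes, with points for the 3 libraries of each genotype and black marks for mean and SD. CG10924, Cyp6a17, Cyp9b2, Cyp28d2 and Lip3 lay higher in the mutant, the others lower, and the wild type points of sha spread from 14.2 to 59.3 CPM.

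In all, 5201 of 11369 genes tested were called (45.7%), 2578 higher and 2623 lower in the mutant, with 732 above 1 and 459 below -1 on the log2 scale. The groups did not overlap for 58.3% of genes tested, where chance gives 10%. At an adjusted p under 0.01 the count was 3069.

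More members rose than fell in the lists of detoxification, digestion, feeding, midgut and neuron genes. Of 95 detoxification genes, 53 rose and 12 fell (53 and 12 adjusted over the list alone), with a median log2 change of 0.64. The glutathione transferase genes GstD10 (log2 1.78, SE 0.06) and GstE5 (2.21, SE 0.09) were among the risers. Of 41 digestive enzyme genes, 29 rose and 2 fell (29 and 2 adjusted over the list alone), among them Jon65Aii (1.89, SE 0.15) and CG5932, the lipase gene magro (1.65, SE 0.11). Of 27 genes known to follow feeding and insulin signalling, 16 rose and 1 fell (19 and 1 adjusted over the list alone), including fbp, a gluconeogenesis gene (0.85, SE 0.06), and GNBP3 (0.79, SE 0.07). The camera test gave adjusted p = 7.66e-08, 1.81e-08 and 7.17e-06 for these 3 lists, and adjusted p = 0.502, 0.502 and 0.483 with an estimated correlation. Midgut markers rose in 7 of 13 and fell in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.0199, adjusted p = 0.585 with an estimated correlation), including the gut transcription factor gene cad (0.76, SE 0.09). Neuron markers rose in 11 of 26 and fell in 1 (11 and 1 adjusted over the list alone, camera adjusted p = 0.0333, adjusted p = 0.483 with an estimated correlation), with unc-13 at 0.77 (SE 0.09). Without wild type A, camera gave adjusted p = 0.0634 for midgut and 0.053 for neuron markers.

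More members fell than rose in the lists of splicing and RNA decay. Of 33 core spliceosome genes, 28 fell and 0 rose (29 and 0 adjusted over the list alone), with a median log2 change of -0.45. SmB fell from 50.1 ± 2.07 to 28.2 ± 2.04 CPM (SD, n = 3 each). Of 30 SR proteins and splicing regulators, 17 fell and 2 rose (17 and 2 adjusted over the list alone), among them Hrb87F (-0.97, SE 0.10) and nito (-0.62, SE 0.05). The mutated gene SRm160 is itself a member that fell. RnpS1, which also fell, belongs both to this list and to the next. Of 16 genes listed for the exon junction complex and nonsense-mediated decay, 10 fell and 0 rose (10 and 0 adjusted over the list alone). The 16 include Gadd45, a target of that decay. The junction complex gene mago fell from 74.0 ± 0.408 to 23.5 ± 2.7 CPM (SD, n = 3 each), its partner tsu by 0.53 (SE 0.06) and eIF4AIII by 0.71 (SE 0.08) on the log2 scale. Camera gave adjusted p = 7.14e-08, 0.00167 and 0.0017 for these lists, and adjusted p = 0.502, 0.483 and 0.483 with an estimated correlation.

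Of 40 cell cycle genes, 26 fell and 0 rose (27 and 0 adjusted over the list alone, camera adjusted p = 3.01e-07, adjusted p = 0.483 with an estimated correlation). Topoisomerase gene Top2 (-0.85, SE 0.09), cyclin gene CycA (-0.72, SE 0.08) and Orc1 (-0.82, SE 0.10) were among them. Of 21 ribosome assembly genes, 6 fell and 0 rose (3 and 0 adjusted over the list alone, camera adjusted p = 0.00635, adjusted p = 0.641 with an estimated correlation), led by Nlp (-1.04, SE 0.08). Of 24 muscle markers, 12 fell and 0 rose (13 and 0 adjusted over the list alone, camera adjusted p = 0.024, adjusted p = 0.502 with an estimated correlation), including the calcium pump gene Ca-P60A (-0.50, SE 0.04). Of 20 heat shock and chaperone genes, 6 fell and 1 rose (5 and 1 adjusted over the list alone, camera adjusted p = 0.0283, adjusted p = 0.585 with an estimated correlation), with Hsc70-3, the endoplasmic reticulum chaperone, at -1.39 (SE 0.14). Without wild type A the adjusted p was 0.0589 for ribosome assembly and 0.093 for heat shock genes, and without mutant A it was 0.0521 for muscle markers.

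Histone genes rose in 89 of 115 and fell in 2 (95 and 2 adjusted over the list alone, camera adjusted p = 6.35e-26, adjusted p = 0.0444 with an estimated correlation). The copies of each histone are near-identical, so their single values are uncertain and the members of the list are not independent. With copies summed by family, camera at the preset correlation gave adjusted p = 0.0135 for the list. With copies summed, a choice made after seeing the data, His2A went from 21.5 ± 0.532 to 175.5 ± 12.8 CPM, His4 from 9.9 ± 1.45 to 39.9 ± 5.62, His1 from 45.3 ± 3.95 to 92.5 ± 4.23 and His2B from 50.3 ± 7.06 to 84.6 ± 9.86 CPM (SD, n = 3 each), all with edgeR adjusted p of at most 0.00442. His3 did not pass (8.56 ± 3.96 and 15.9 ± 4.28 CPM, adjusted p = 0.0705). Whether single reads were counted in several copies is not known, and if so these sums count them repeatedly.

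**Figure D2:**
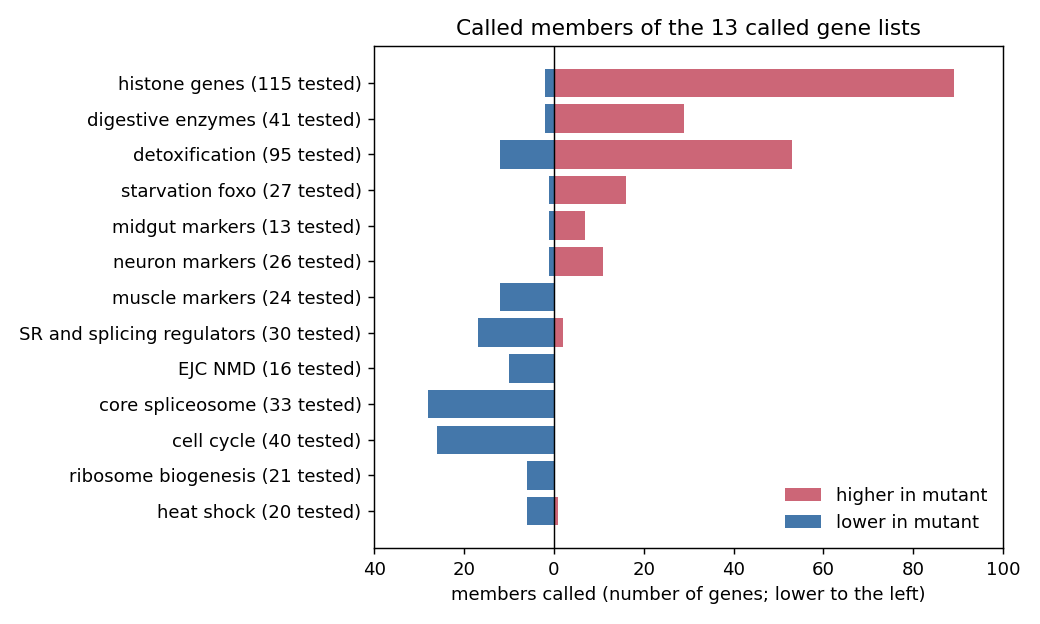
Number of members called higher (right) and lower (left) in the mutant for each of the 13 called gene lists, with the number tested in parentheses. Histone genes had 89 higher and 2 lower of 115, and core spliceosome genes 0 higher and 28 lower of 33.

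Camera called 13 of 35 lists, 6 up and 7 down, and only the histone list, with its near-identical copies as separate members, held with an estimated correlation. Its adjusted p with an estimated correlation, a combination chosen after seeing the data, was 0.127 without wild type A, 0.0531 without wild type B, 0.281 without wild type C, 0.129 without mutant B, 0.246 without mutant C and 0.327 with a minimum mean CPM of 1, and the call held without mutant A (0.039). Other splits of the 6 libraries into 3 and 3 gave from 4 to 17 called lists, so the number of called lists does not set the genotype comparison apart from them. Each other split mixes the genotypes unevenly, so part of the genotype difference stays in it and these counts are not free of genotype.

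Splicing was compared through the usage of each bin relative to its locus. Some bins were used almost only by a single genotype. Exonic bin E007 of CG8195, annotated as a transcript end (2R, 11453079 to 11453291), had 0 counts in wild type and 5.48% ± 0.93 of locus counts in the mutant (SD, n = 3), at least 54.9-fold higher against 3 counts over the wild type group. Bin E002 of SdhC, a subunit gene of succinate dehydrogenase, also a transcript end (3R, 7035520 to 7035571), fell from 7.29% ± 0.335 to 0.126% ± 0.0556 (SD, n = 3 each). In bol, E015 (3L, 9122997 to 9123452) fell from 2.02% ± 0.187 to 0.0761% ± 0.0257. In all, 1011 of 49599 exon bins tested were called, 516 higher and 495 lower, in 531 loci.

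Intron bins changed in both directions. Intron I006 of CG10936 (2R, 13499087 to 13502404) rose from 0.0479% ± 0.0201 to 4.47% ± 0.313 of locus counts, and I011 of CG34114 (3R, 6860648 to 6865632) from 0.152% ± 0.205 to 14.9% ± 0.927 (SD, n = 3 each). Intron I002 of CG1347 (3R, 1502283 to 1502990) fell from 2.13% ± 0.347 to 0.0537% ± 0.0466, and I002 of CG14375 (3R, 9216018 to 9217586) from 1.2% ± 0.242 to 0.0838% ± 0.0828. In Cyp28d2, whose gene counts rose, I004 (2L, 5208651 to 5208720) fell from 4.36% ± 0.275 to 0.248% ± 0.0536 of locus counts with mean counts of 34 and 36.7. Of 13953 intron bins tested, 803 were called, 462 higher and 341 lower, and with voom 1208, 704 higher and 504 lower. Of the 803, 183 overlapped an exonic bin of their own gene, so that exonic reads count in them, and 620 did not, among them the 5 just named. With the overlapping bins left out of the test, a choice made after seeing the data, 598 were called, 349 higher and 249 lower. Bins I001 of SNF4Agamma, I019 of Tequila and I004 of desat1 are of the overlapping kind and are not read here as changes of introns. Of the 803, 10.5% overlapped an exon of another gene, against 5.96% of the other intron bins.

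Among alternative bins, the retained intron E004 of CG14642 (3R, 67421 to 67476) rose from 0.532% ± 0.447 to 8.06% ± 0.316 and the skipped exon E008 of PMCA, a calcium pump gene (4, 358162 to 358173), from 0.014% ± 0.0161 to 0.219% ± 0.0268 (SD, n = 3 each). The skipped exon E010 of Tequila (3L, 9078158 to 9078400) fell from 1.68% ± 0.0693 to 0.0145% ± 0.0252. Exonic bins E009 and E012 to E024 of Tequila fell as well, each by more than 3 (log2, relative to the gene). Bin E007 rose by 3.07. The fall is therefore not read as skipping of E010 alone. Of 4272 alternative bins tested, 190 were called, 104 higher and 86 lower. Skipped exons were called in 75 of 1322 (47 higher, 28 lower), retained introns in 24 of 668 (8 higher, 16 lower), alternative 5' sites in 29 of 617 and alternative 3' sites in 18 of 534. Without mutant B the counts were 541 exon, 501 intron and 119 alternative bins, and without wild type B 642 exon bins. With the gene count as offset there were 1618 exon bins, and with bins that overlap no other gene, chosen after seeing the data, 623.

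**Figure D3:**
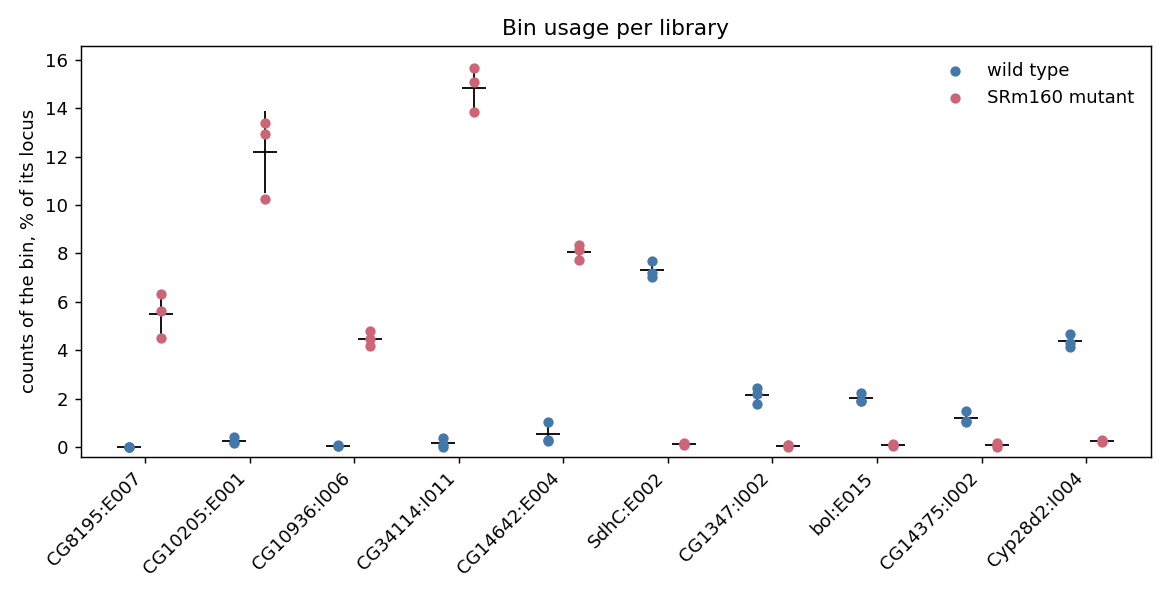
Counts of 10 bins as a percent of all bin counts of their locus, with points for the 3 libraries of each genotype and black marks for mean and SD. CG34114:I011 lay at 14.9% in the mutant and 0.152% in wild type on average, SdhC:E002 at 0.126% and 7.29%.

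Called bins with a log2 change above 3 in size numbered 128 in 83 loci. Within 5 Mb of SRm160 lay 29 of them (22.7%), against 7.76% of the other bins tested (Fisher's exact test, two-sided, odds ratio 3.48, 95% interval 2.22 to 5.32). Most of the 29 were bins of the same locus, Tequila. Several bins of a locus are not independent: counted by locus, 12 of 83 lay in that window (14.5% against 8.02%, Fisher's exact test, p = 0.0413, odds ratio 1.94, 95% interval 0.952 to 3.62), a count chosen after the result by bins was seen. By arm, large bins made up 0.276% of bins tested on 3L, 0.236% on 3R, 0.208% on 2R, 0.121% on 2L, 0.0783% on 4 and 0.0733% on X. The share on 3L includes the bins of Tequila, and the share on 3R includes several bins each of CG9813, CG31352 and unc-115.

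**Figure D4:**
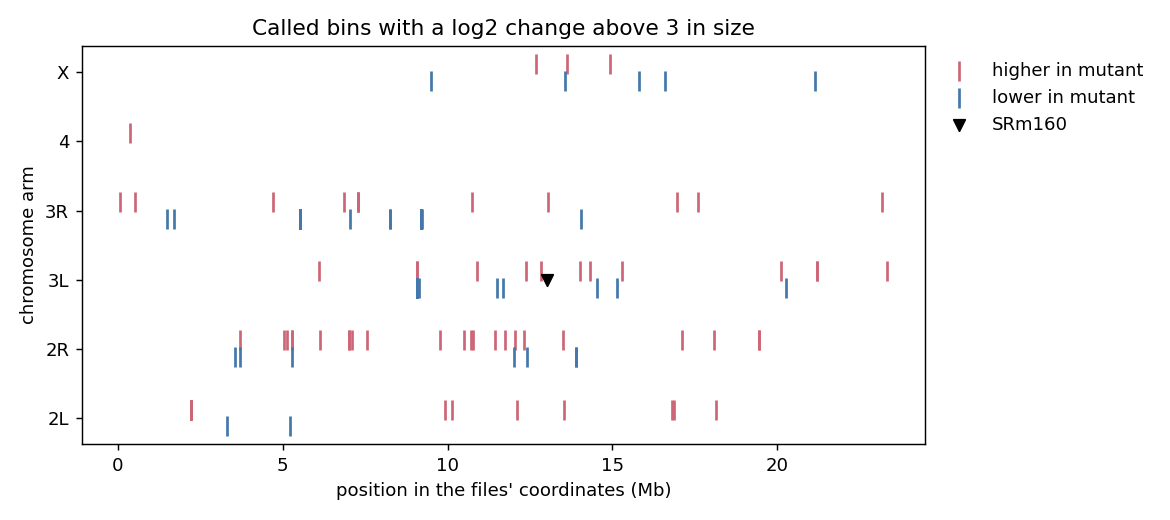
Start position in Mb, as the deposited tables give it, of the 128 called bins with a log2 change above 3 in size on each chromosome arm, red for higher and blue for lower in the mutant. The black triangle marks SRm160 on 3L, where 35 of the bins lie, many of them in Tequila.

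The share of counts in intron bins was compared over whole libraries. Part of these counts was exonic, since bins that overlap an exonic bin of their gene held from 34.3% to 35.0% of them. The share was 7.78% ± 0.24 in wild type and 8.47% ± 0.16 in the mutant (SD, n = 3 each), higher in each mutant library than in each wild type library, by 0.689 percentage points (exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 allows). Without the 100 highest intron bins the difference was 0.283, with intron bins that overlap no exon of another gene, chosen after seeing the data like the next 2, 0.388, with those that overlap none of their own gene 0.494, with those that overlap none of any gene 0.282, and for the median gene 0.0217 percentage points (exact permutation test, p = 0.6).

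Sex-specific splicing was examined in tra, dsx, fru and msl-2. Sxl was planned as well, but with all libraries none of its bins was among those tested. Of 28 bins tested, 2 were called, both in fru: E014, annotated as a transcript end (3R, 14272423 to 14273051), rose by 0.72 on the log2 scale relative to the gene (edgeR adjusted p = 0.0408), and intron bin I010 (3R, 14264422 to 14272422), which overlaps exonic sequence of fru, fell by 1.66 (edgeR adjusted p = 0.0266). At an unadjusted p under 0.05 there were 6. The number called with edgeR was 4 without wild type A and 0 without any other single library, where from 3 to 8 had an unadjusted p under 0.05. With intron bins that overlap exonic bins of their gene left out, a choice made after seeing the data, 0 of 21 bins were called with edgeR (2 at an unadjusted p under 0.05), and E014 had adjusted p = 0.0748. With voom 1 of the 28 was called.

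Loci with a called bin were more often called as genes. Of 1029 such loci tested in both ways, 567 were called as genes (55.1%), against 46.7% of the others (Fisher's exact test, two-sided, odds ratio 1.40, 95% interval 1.23 to 1.60, p = 4.65e-07). Among loci with a mean count of 1000 or more the odds ratio was 1.12 (Fisher's exact test, p = 0.162).

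The authors' deposited table of altered genes lists 1093 genes, 678 higher and 415 lower, all with a log2 fold change of at least 1 in size. Of these, 1087 were tested here and 1046 were called (95.7%), and the sign was the same for all 1087. The authors' deposited tables of bins list 341 alternative, 1634 exon and 1120 intron bins, of which 311, 1504 and 904 were tested and 151, 713 and 434 called here. The largest FDR in the authors' deposited tables of bins was 0.0998, against the threshold of 0.05 here, and the sign was the same for 310 alternative, 1499 exon and 903 intron bins of those tested. In the authors' deposited summary of enriched terms, proteolysis (p = 3.1e-13) and oxidation reduction (p = 1.63e-10) led for the higher genes, and oxidation reduction (p = 0.000191) for the lower genes. Both analyses rest on the same libraries.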

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

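Alternatives restricted to bins or genes without overlap, with the gene's own exonic bins or with other genes, those with histone copies summed, and the estimated correlation combined with a library left out or a minimum CPM, were chosen after seeing the data. The direction of change held for the 148 named genes and 32 named bins under each alternative run for them, and no called list turned around. Lists that passed under neither setting were not followed for direction. Calls were lost for 55 of the 148 genes under at least 1 alternative and for 2 of the 32 bins, both of fru.

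The count of 5201 genes became 3069 at an adjusted p under 0.01 and 2604 with a minimum log2 change of 0.58, which construction alone makes smaller. It was 5496 with DESeq2 and 5216 with voom, and from 3504 to 5206 with a library left out. SRm160 stood at -0.34 throughout the tools and at -0.38 to -0.31 with a library left out, and failed the minimum of 0.58 in size (-0.34). Exon bins went from 1011 to 1618 with the gene count as offset, to 623 with bins that overlap no other gene, to 910 without intron bins that overlap their gene's exonic bins, and from 541 to 1201 with a library left out. Intron bins went from 803 to 1208 with voom and from 501 to 901 with a library left out, alternative bins from 190 to between 119 and 200. Of the bins called with the offset, 1161 of 2897 were shared with the 2004 called here. Called lists numbered 13, 1 with an estimated correlation, from 0 to 1 with that and a library left out (from 12 to 14 at the preset correlation), 0 with that and a minimum mean CPM of 1, and 21 with fry, which does not compare a list with other genes. Called bins of sex determination genes were 2, 1 with voom, 1 with the replicate block, 0 without intron bins that overlap exonic bins of their gene (2 at an unadjusted p under 0.05, edgeR), and from 0 to 4 with a library left out. The odds ratio of 1.40 became 1.12 in loci with a mean count of 1000 or more. For these changes the cause was not tested.

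The labels share the letters A, B and C between genotypes, and libraries with the same letter did not deviate together (correlations across genes of -0.435, -0.442 and -0.0951), so the letters were not taken to pair them. With the letter as a replicate block, 4272 genes, 874 exon, 689 intron and 163 alternative bins and 13 lists were called, and SRm160 had adjusted p = 0.0252. No library correlated best with its own letter. At these depths and with 3 libraries per group, simulation recovered 11.2% of genes changed by 0.5 and 67.7% of those changed by 1 on the log2 scale, and what part of this depth sets was not tested. The simulation changed only 98 and 99 of 11297 genes, whereas 5201 of 11369 were called here, so its adjusted threshold was stricter. These shares are therefore not the power of this comparison.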

Other observations

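The tests of RNA from mutant larvae, S phase, RNA without poly(A), shared histone reads, overlapping genes and intron removal, the comparison of pairs of mutant libraries, the estimated correlation with a library left out or with a minimum mean CPM, and the counts of loci and of genes near SRm160, were chosen after the results were seen.

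Outside the called lists, glycolysis genes rose in 8 of 14 and fell in 0 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0906), including Hex-A (0.84, SE 0.07) and Gpdh (0.81, SE 0.08). Chitin genes rose in 12 of 23 and fell in 5 (13 and 5 adjusted over the list alone, camera adjusted p = 0.0829, and 0.0499 without mutant A, where adjusted p = 0.523 with an estimated correlation): Cht6 rose by 1.46 (SE 0.10) and Cht9 by 2.35 (SE 0.31), while Cht3 fell by 1.37 (SE 0.11) on the log2 scale. Ecdysone response genes fell in 12 of 23 and rose in 6 (12 and 6 adjusted over the list alone, camera adjusted p = 0.0906). Blimp-1 fell by 2.09 (SE 0.26) with Hr46, whereas Eip74EF rose by 1.25 (SE 0.14). Without wild type A the list passed camera (adjusted p = 0.00428), as did trachea markers (0.00719) and late embryo genes (0.0406). For these 3 lists without wild type A, adjusted p = 0.526, 0.526 and 0.599 with an estimated correlation. Glia markers rose in 4 of 10 and fell in 0 (4 and 0 adjusted over the list alone, camera adjusted p = 0.0906), with Gs2 at 1.06 (SE 0.07) and Indy at 1.05 (SE 0.10).

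In the other lists, none of which passed camera, the members called higher and lower are given with those adjusted over the list alone in parentheses. Called members were, for ribosomal proteins 4 and 5 of 84 (1 and 3), oxidative phosphorylation 4 and 5 of 76 (0 and 3), cuticle proteins 15 and 17 of 93 (15 and 15), sex determination 1 and 3 of 20 (0 and 2) and ecdysteroid synthesis 3 and 0 of 13 (3 and 0). Further numbers were, for juvenile hormone 3 and 0 of 10 (0 and 0), melanin and tyrosine 9 and 1 of 29 (8 and 1), fat body and storage 4 and 1 of 12 (4 and 1), antimicrobial peptides 3 and 1 of 17 (2 and 1) and cell death 4 and 5 of 14 (4 and 5). Cell type markers gave, for hemocyte 2 and 6 of 14 (2 and 6), Malpighian tubule 4 and 3 of 10 (5 and 3), trachea 2 and 7 of 14 (2 and 7), salivary gland 1 and 3 of 6 (1 and 3) and imaginal disc 6 and 2 of 20 (5 and 2). Last came, for germ line 0 and 1 of 12 (0 and 0), late embryo 2 and 5 of 13 (2 and 7) and small noncoding RNA 22 and 38 of 189 (22 and 24). For cell death genes the median log2 change was 0.15 and the mean -0.12. The small noncoding RNA list passed without mutant C (adjusted p = 0.0117, and adjusted p = 0.629 with an estimated correlation), and the melanin list with a minimum mean CPM of 1 (adjusted p = 0.0363, and adjusted p = 0.466 with an estimated correlation).

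Wild type A lay apart from wild type B and C. With libraries thinned to equal totals, the SD of its log2 differences from B and C was 2.75 times that of B from C, which argues against depth. RNA of mutant larvae is also argued against: w had 0 counts in wild type A, and 3 counts allow at most 0.37% of mutant RNA, against a median shift toward the mutants of 3.76% with quartiles of -21.0 and 34.4, wide apart where mixing would give 1 share. The 124 members of the ecdysone, cuticle and late embryo lists differed by a median of 0.71 (log2, regardless of sign) between A and the mean of B and C, above all 10000 random lists matched on expression (percentile 100, median 0.20). A spread of developmental age between pools would give this. The random lists were not matched on how far genes vary or vary together, so any other shared difference could give it too. The percentile therefore does not single out age. Inside the mutant, the differences A minus B, A minus C and B minus C correlated at -0.51, -0.30 and 0.25 across genes, which are not independent, with the difference of wild type A from B and C, and part of the falls in molting genes may reflect age, and a shift of the mutants in age stays open.

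Histone transcripts were higher in the mutant. A shift of reads between copies of a family leaves the sum of the family unchanged, and 4 of 5 families passed with copies summed. Whether single reads were counted in several copies is not known. If so, the sums count them repeatedly, and the adjusted p of the families may be too small. The cell cycle list showed no rise that more cells in S phase would give, with a median of -0.46, 26 members lower and 0 higher. It mixes genes of mitosis with genes of DNA replication and did not pass with an estimated correlation (camera adjusted p = 0.483). The list therefore cannot decide whether more cells were in S phase. More RNA without poly(A) cannot be told apart from a change in histone transcripts: small noncoding RNA outside histone genes had a median of -0.49 (camera adjusted p = 0.00432, adjusted p = 0.696 with an estimated correlation), and such short RNA can be lost in library preparation. An effect of the SRm160 mutation on histone transcripts stays open as an untested hypothesis.

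Bins that changed relative to their gene may mix effects of the mutation with differences between strains. Reads of overlapping genes cannot be the whole source, since 13.6% of called bins overlapped another gene against 9.5% of the others. For bins on its chromosome, strain differences linked to SRm160 cannot be told apart from the mutation: large bin changes were more frequent within 5 Mb of it by bins, the measure set beforehand (odds ratio 3.48, Fisher's exact p = 1.45e-07), and by loci p was 0.0413 with an interval that included 1, while 7.69% of large gene changes lay near it against 8.43% of other genes (Fisher's exact p = 0.875). A general fall in intron removal stays open, since the values go both ways: 8 of 24 called retained introns were higher (exact binomial p = 0.152), whereas intron bins were called higher in 462 and lower in 341, and the share of counts in intron bins was higher in each mutant library by 0.689 percentage points on average but by 0.0217 for the median gene (exact permutation p = 0.1 and 0.6). Of the large bins within 5 Mb of SRm160, most were bins of Tequila, so the result by bins leans on that locus. Other chromosomes held 53 of the large bins, and strain differences there were not tested.

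The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Each other split mixes the genotypes unevenly, so part of the genotype difference stays between its groups and part adds to the spread within them. The real split gave 5201 genes and the highest other 0; 1011 exon bins and 8; 803 intron bins and 8; 190 alternative bins and 3; and 2 sex determination bins and 0. For each of these 1 split of 10, the real one, reached the real value. For gene lists 3 splits of 10, the real one included, reached 13, and the highest other gave 17. The odds ratio of loci called for a bin and as a gene was 1.40, and no other split called a gene, so none gave a ratio above 0.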
